A study of Mus musculus with 8 samples.

How the data were processed

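Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for the transcription factors NFIA, NFIB and NFIX in granule neuron progenitors, the dividing cells that give rise to cerebellar granule neurons, taken from mice at postnatal day 7. Each factor had 2 libraries, 1 from CD1 mice and 1 from mice of a mixed background that the labels describe as resembling outbred CD1. The series has 8 samples. The 2 input samples were not analysed here. For NFIB the sample labels name a Novus Biologicals antibody and the series design text names a Sigma antibody, and which of them was used is not settled here. Nothing in the labels says that the libraries came from separate animals or cultures, so p-values across libraries measure only the spread between these samples, which may be technical. Libraries are named below by factor (NfiA, NfiB, NfiX) and background (CD1, Mixed), and replicate 1 of a factor is its CD1 library and replicate 2 its Mixed library.

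Bowtie2 2.2.6, SAMtools 1.4.1 and MACS2 2.1.0 and the genome build mm10 are named in the submitters' processing notes. Whether the input samples served as controls, which reads were filtered and which threshold was set are not given in the sources used here. The authors deposited 1 peak list per library, with no list over pooled samples. Each peak carries a fold enrichment at its summit over the local background, a ratio made by the authors. The deposited lists also give a −log10 p-value and a −log10 q-value per peak, both from the authors' peak caller. The deposited score column is an integer and was not used here. The highest q-value in a list, computed from the deposited −log10 q, was 0.0411 to 0.0492. Folds and q-values are the authors' own and were used only to describe, rank or filter peaks within a list.

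Read totals were not among the files used here, so depth was judged from the peaks. A whole number of fragments and a local background that together give the deposited fold and p under a Poisson model were found for 100% of the peaks of each library, within a tolerance of 0.002 on the −log10 p scale. After the p-values of 1000 peaks per library were shifted at random, 0 to 0.7% still matched. The median summit held 21 to 28 fragments, and the lowest local background, 0.856 fragments in NfiX CD1 to 1.39 in NfiB Mixed, was taken as an index of depth. Intervals on shares are 95% Wilson intervals, except that a share of 0 is given the limit that 3 counts of its total would reach. Both cover counting error only.

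Peaks that overlapped by at least 1 bp were merged over the 6 lists into union regions, and a region was called common when it held a peak of all 6 libraries. Overlap was compared with 100 random placements of the peaks on their own chromosomes, between the first and last gene or peak, since no chromosome lengths were used. Libraries were compared by the Jaccard index, shared bases over all bases covered, with an exact permutation over the 6 ways to match CD1 with Mixed libraries (smallest possible p 0.167). Values over the 6 libraries were tested with an exact two-sided sign-flip permutation (smallest possible p 0.0312, and 0.0625 with 1 library left out). Genes came from the GENCODE mouse annotation on the same build. A region was assigned to the protein-coding gene with the nearest transcription start site (TSS) within 100 kb, which names a neighbour and not a target. Promoters were summits within 1 kb of a protein-coding TSS.

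The motif test was planned on the whole genome sequence. No genome sequence was used here, so 101 bp windows around summits were read from transcript sequences where they lay inside annotated exons. They were compared with exonic windows 1 kb to each side that touched no peak, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 126 tests of 21 motifs, 2 of them controls. Odds ratios of summits against flanks carry a continuity correction, and those between sets of regions do not. Where no flanking window and more than 3 summit windows held a motif, as for the NFI palindrome in NfiX CD1 and in common regions, the odds ratio was instead computed against a floor of 3 counts over the library or region set and is a lower bound. This floor was chosen after the counts had been seen. Gene lists, 21 in all with 403 entries, each matched to the annotation, were compared with 10000 random lists matched on the length of genome nearest to each gene's TSS in 20 bins, two-sided, with Benjamini-Hochberg adjustment over the lists. Genes are not independent replicates, so these p-values describe these regions only.

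The lists, the motifs, the main tests of overlap, strength, promoters, motifs and gene lists and the rule for named genes were fixed before the data were examined, except for the exonic windows and the floor named above. The tests of families and some of those in the closing observations were chosen later. The rule names the 25 genes whose common region had the highest mean percentile of fold over the 6 libraries, the 4 Nfi genes, up to 4 top-ranked members of each list with members lacking a region where a statement is about them, and the 5 genes with the highest-ranked regions of each factor alone. Genes ranked by their number of common regions, and families grouped by symbol, were chosen after their values were seen.

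On simulated lists with 1500 planted shared regions, 1500 were found in all 6 lists, and a full search of a small case gave the same 1501 overlapping peaks as the function used. In 50 simulated runs over 21670 genes, 1 of 1050 list tests was called with no effect present. Genes with a region were drawn there by the same length of genome that the random lists were matched on. The runs therefore cannot show how often lists are called where regions also follow other features of genes. For the axon guidance list of 35 genes, adding up to 5 members with a region gave a call in 6 runs, adding up to 10 in 33 and adding up to 15 in 50. Alternatives covered the overlap required, a −log10 q of 5 or more, lists of equal length (7497 peaks), each background alone, each library left out, other gene assignments, other windows and other backgrounds. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.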

Results

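The libraries held between 7497 and 36431 peaks. NfiB had the longest lists, 36431 peaks in CD1 and 33283 in Mixed, covering 13.5 and 12.3 Mb. NfiA had 16993 and 23541 peaks, covering 5.36 and 7.55 Mb. NfiX had 7497 peaks in CD1 and 21443 in Mixed, covering 1.99 and 6.69 Mb. Median peak widths were 244 to 321 bp, and median fold enrichments were 5.51 to 6.03. The median summit held 21 fragments in NfiX CD1 and 28 in both NfiB libraries.

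**Figure D1:**
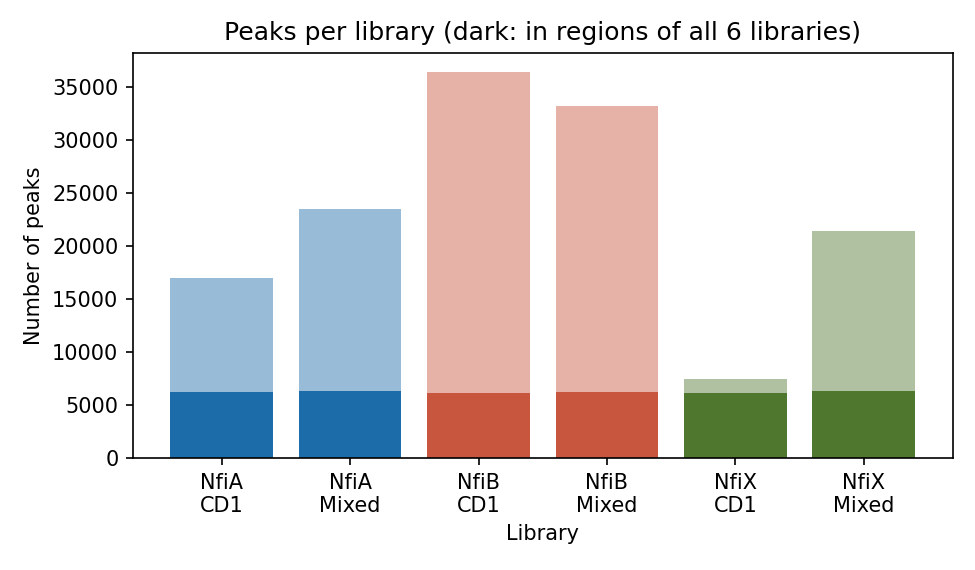
Number of peaks (vertical axis) in each of the 6 libraries (horizontal axis), with the dark part of each bar counting peaks in regions common to all 6 libraries. The dark part is 6170 to 6322 peaks in every library, which is 16.9% of the NfiB CD1 list and 82.7% of the NfiX CD1 list.

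The first question was whether the sites of a factor recurred between the backgrounds. For NFIA, 13992 of the 16993 peaks of the shorter list overlapped a peak of the other library, a share of 82.3% (95% Wilson interval 81.8 to 82.9). For NFIB the share was 79.6% (79.2 to 80.02, 26491 of 33283 peaks), and for NFIX it was 93.1% (92.5 to 93.6, 6978 of 7497 peaks). Random placement gave means of 0.614%, 1.08% and 0.508%. No placement reached the observed share (permutation of peak positions, p = 0.0099 for each factor, the smallest that 100 placements can give). The placements spread peaks evenly along chromosomes, so passing shows only that peak positions were not spread in that way. Pairs of libraries of different factors shared 88.1% of the shorter list on average, so this recurrence was not particular to a factor. The high NFIX share went with the short NfiX CD1 list. With 7497 peaks taken from every library the shares were 72.1% for NFIA, 77.2% for NFIB and 67.8% for NFIX. With the peaks of each library in 4 equal groups by fold, the highest group recurred most often in 6 of 6 libraries. From the lowest to the highest group the share found in the other library of the factor went from 72.4 to 96.3% for NfiA CD1, 34.0 to 89.8% for NfiA Mixed, 51.6 to 96.9% for NfiB CD1, 63.9 to 97.2% for NfiB Mixed and 6.83 to 73.6% for NfiX Mixed. For NfiX CD1 peaks the groups were at 91.6, 89.2, 93.4 and 98.2%.

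The series title concerns targets shared by the 3 factors. The 6 lists merged into 46070 regions, of which 6062 (13.2%) held a peak of all 6 libraries. None of 100 random placements gave a single such region, and independent membership within the union would give 336. The placements spread peaks evenly, and the independent count takes no account of peak strength. Neither can test whether the factors share targets. The NfiX CD1 list limited the number of common regions: without that library 11643 regions held a peak of all the others. With equal list lengths 3350 regions were common, and the Mixed libraries alone shared 15890. Common regions were 590 bp wide at the median, against 311 bp for the rest. Because a merged region spans all its peaks, common regions are wider in part by definition. Within them, summits of a pair of libraries lay a median of 21.7 ± 2.3 bp apart for pairs of the same factor (SD, n = 3 pairs), 22.3 ± 2.0 bp for pairs of the same background (n = 6 pairs) and 22.5 ± 2.0 bp for the other pairs (n = 6 pairs).

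The highest-ranked common regions lay in or near genes of varied function. The top region was in an intron of Scml4 (chromosome 10, 42863360 to 42864064), 2.89 kb from its TSS, with folds of 25.7 to 41.0 over the 6 libraries. The next lay 30.4 kb upstream of Irs2, an adaptor of insulin signalling, in an intron of a gene that is not protein-coding (chromosome 8, 11038555 to 11039175, folds 25.7 to 41.3). An intron of Nsd3, a histone methyltransferase gene, held a region at chromosome 8, 25619994 to 25620549, and an intron of Zbtb16, which encodes a zinc finger transcription factor, held one at chromosome 9, 48740015 to 48740592. The region at Prss12, a neuronal serine protease gene, overlapped a UTR (chromosome 3, 123506150 to 123506934). The cannabinoid receptor gene Cnr1 held an intronic region 10.2 kb from its TSS (chromosome 4, 33936167 to 33936789, folds 25.4 to 36.2). Introns of the cell polarity gene Pard3 (chromosome 8, 127099569 to 127100248) and of Srgap2, a regulator of neuronal morphology (chromosome 1, 131357088 to 131357502), were also among the 25. The others were assigned to Oit1, Fam49b, Scube2, Cse1l, Il12b, Rps20, 1700003H04Rik, Crybg3, Olfr221, Stxbp5l, Stoml3, Vwc2, Dnajc5b, Frem1, B3galt2, Ccdc141 and Cdh7. Several of these names are only the nearest TSS: the Oit1 region lay in an intron of 4930452B06Rik, the Cse1l region within Stau1 at a noncoding exon and the Stoml3 region in an intron of Frem2. The lowest mean percentile of fold over the 6 libraries among these 25 regions was 99.2.

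Of the 4 NFI genes, 3 had common regions nearby. Nfia was nearest to 6 common regions, Nfib to 4 and Nfic to 4. The highest-ranked Nfia region (chromosome 4, 97775980 to 97777227) lay where the gene overlaps E130114P18Rik on the other strand, 1.10 kb upstream of the nearest Nfia TSS, with folds of 11.8 to 19.6. E130114P18Rik was itself nearest to 6 common regions, so regions of this locus cannot be given to 1 of these genes. The Nfib region was intronic (chromosome 4, 82494387 to 82496092, folds 8.07 to 15.9), as was the Nfic region (chromosome 10, 81435324 to 81435935, folds 10.8 to 13.4). Nfix was nearest to no common region. It was nearest to 2 regions with a peak in NfiA CD1, 5 in NfiA Mixed, 7 in NfiB CD1, 8 in NfiB Mixed, 0 in NfiX CD1 and 2 in NfiX Mixed. As a list, 3 of the 4 family members had a common region against 0.991 in matched random lists (permutation test, adjusted p = 0.217).

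**Figure D2:**
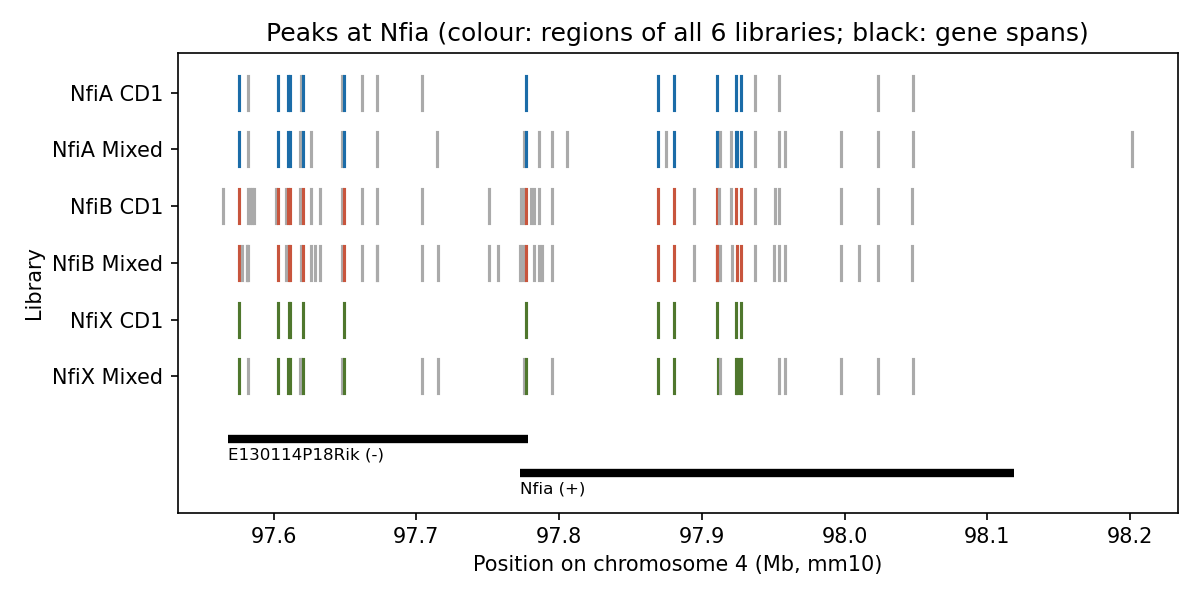
Peaks of each library (vertical axis) by position on chromosome 4 in Mb (horizontal axis, mm10) around Nfia, with coloured ticks for peaks in regions common to all 6 libraries, grey ticks for other peaks and black bars for gene spans. NfiX CD1 had 12 peaks in this window and NfiB Mixed 48.

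Whether libraries resembled each other by factor was not resolved. The mean Jaccard index was 0.428 ± 0.149 for pairs of the same factor (SD, n = 3 pairs), 0.380 ± 0.145 for pairs of the same background (n = 6 pairs) and 0.336 ± 0.123 for the rest (n = 6 pairs). The matching by factor had the highest mean of the 6 matchings, at p = 0.167 in the exact permutation test, the smallest this design allows. The order turned when the share of the shorter list was used: it was 85.0% for the same factor, 89.2% for the same background and 87.1% for pairs sharing neither, a difference of −2.06 percentage points between the first and the last (exact permutation p = 0.833). With lists of equal length these shares were 72.4%, 73.2% and 67.6%, and the difference between the first and the last was 4.74 points (exact permutation p = 0.167).

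Regions seen in both libraries of a factor numbered 13713 for NFIA, 26091 for NFIB and 6844 for NFIX. Of the NFIX regions 94.4% (95% Wilson interval 93.8 to 94.9) and of the NFIA regions 95.8% (95.4 to 96.1) were also NFIB regions. In the other direction, 50.3% of the NFIB regions were NFIA regions and 24.8% were NFIX regions. With a peak in at least 1 library of the other factor these shares were 78.3% and 65.1%. The latter no longer required a peak in NfiX CD1, the shortest list. The high shares of NFIA and NFIX regions that were NFIB regions depend on the longer NfiB lists. With 7497 peaks per library, 77.4% of NfiA CD1 and 65.4% of NfiX CD1 peaks overlapped a NfiB CD1 peak, and 76.5% and 63.8% in reverse. In Mixed, 79.0% of NfiA and 75.2% of NfiX peaks overlapped a NfiB peak, and 78.5% and 74.6% in reverse. Regions of 1 factor alone, with peaks in both of its libraries and in none of the other 4, numbered 37 for NFIA, 4484 for NFIB and 56 for NFIX. With 7497 peaks per library they were 83, 161 and 258. The highest-ranked regions of NFIB alone were assigned to Adam12 (chromosome 7, 134171315 to 134171648, intronic, folds 8.54 and 10.3), Gp2, Sh3kbp1, Il1r1 and Phf3. Those of NFIX alone were assigned to Spaca3 (in an intron of Asic2), Adgrl3 (chromosome 5, 81367614 to 81367852, intronic, folds 7.14 and 8.62), Ltbp1, Zfp945 and Prps2. Those of NFIA alone were assigned to Slc2a10 (chromosome 2, 165513302 to 165513534, intronic, folds 6.30 and 6.53), Pik3cb, Erc2, Cdc27 and Mc2r.

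Peaks in common regions had higher fold enrichment than the other peaks of their list in 6 of 6 libraries. The median log2 fold was higher by 1.18 in NfiB CD1, 1.03 in NfiB Mixed, 0.78 in NfiA Mixed, 0.76 in NfiX Mixed, 0.60 in NfiA CD1 and 0.08 in NfiX CD1. The mean difference was 0.74 ± 0.38 (SD, n = 6 libraries; exact sign-flip permutation p = 0.0312, the smallest possible). With peaks of −log10 q of 5 or more only, it was 0.68 and did not pass (exact permutation p = 0.0625). A common region must be called in all 6 lists, which favours stronger peaks. The direction of this difference therefore follows in part from the definition.

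Most sites were distal. Introns of protein-coding genes held 41.1% ± 0.76 of summits (SD, n = 6 libraries) against 35.8% of randomly placed summits, and intergenic sequence held 42.4% ± 2.67 against 51.1%. Promoters held 8.60% of summits in NfiB CD1, 8.12% in NfiB Mixed, 5.44% in NfiA Mixed, 4.21% in NfiA CD1, 3.93% in NfiX Mixed and 2.35% in NfiX CD1, where random placement gave 2.53 to 2.60%. The share was above random in 5 of 6 libraries, with a mean log2 ratio of 0.94 ± 0.69 that did not pass (exact sign-flip permutation p = 0.0625, n = 6 libraries). It did pass with TSSs of all gene biotypes (0.61, exact permutation p = 0.0312), and was 0.11 with promoters taken as 5 kb (exact permutation p = 0.531). In the 7497 strongest peaks of each library, an alternative chosen after the data were seen, promoter shares were 2.35 to 3.47% and the mean log2 ratio was 0.25.

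**Figure D3:**
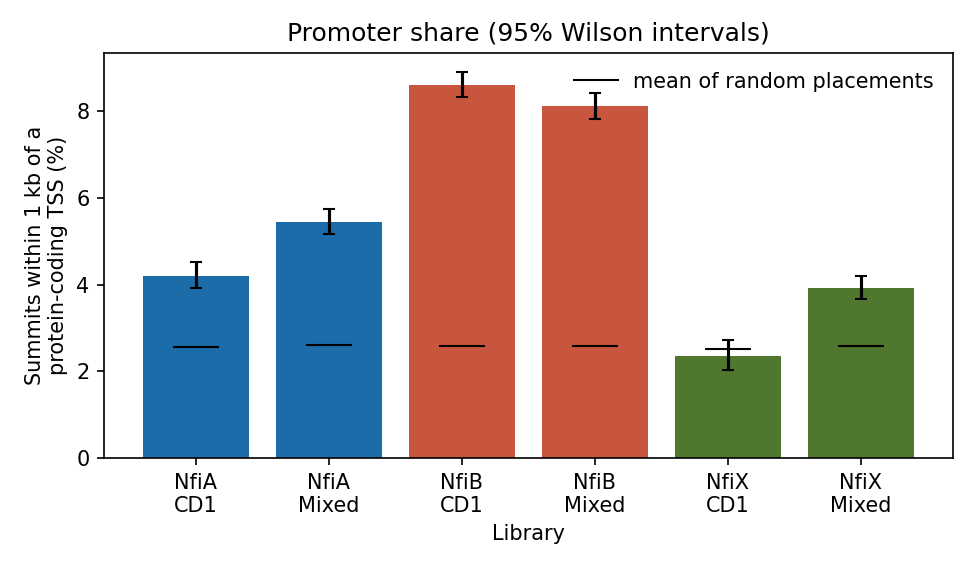
Percent of summits within 1 kb of a protein-coding TSS (vertical axis) per library (horizontal axis), with 95% Wilson intervals as error bars and the mean of 100 random placements as a black line. Both NfiB libraries stand above 8%, and NfiX CD1 lies at 2.35% with a random mean of 2.53%.

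Common regions were less often promoters than the others. Their promoter share was 2.44% (148 of 6062), against 8.11% of regions in 2 to 5 libraries. Of regions in 1 library 11.5% were promoters (1690 of 14690, odds ratio 0.193, Fisher's exact test, two-sided, adjusted p = 1.03e-118). A common region must hold a peak of NfiX CD1, whose own promoter share was 2.35%. The 7497 strongest peaks of each library had shares of 2.35 to 3.47%. This contrast therefore cannot be told apart from list length and peak strength, and the tests here treat regions as independent. Regions of NFIB alone were promoters in 18.6% of cases (834 of 4484), with an odds ratio of 9.13 against common regions (Fisher's exact test, adjusted p = 5.69e-182). This set comes from the longest lists: it held 161 regions with 7497 peaks per library, where promoters took 3.27% and 3.28% of the NfiB peaks and 3.17% and 3.47% of the NfiA peaks, and its promoter share was not computed there. Regions of NFIA alone were promoters in 10.8% of cases (4 of 37, odds ratio 4.84, Fisher's exact test, adjusted p = 0.0148). Among regions of NFIX alone, 0 of 56 were promoters, which allows a share of up to 5.36%. Promoter common regions existed at single genes, such as Nhlh2, which encodes a neuronal bHLH factor (chromosome 3, 102009794 to 102010419), and Vim, the gene of an intermediate filament protein (chromosome 2, 13573634 to 13574210).

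The NFI palindrome, TGGCNNNNNGCCA, was concentrated at summits. In exonic windows it was present at 27.4% of summits in NfiX CD1, 14.6% in NfiX Mixed, 13.3% in NfiA CD1, 10.2% in NfiA Mixed, 5.98% in NfiB CD1 and 5.37% in NfiB Mixed. The share was highest in the shortest list, NfiX CD1, and lowest in the long NfiB lists. These shares therefore cannot tell a difference between factors from one of list length. Flanking windows held the palindrome in 0.192 to 0.365% of cases in 5 libraries and in 0 of 460 in NfiX CD1, which allows up to 0.652%. Odds ratios were 18.9 to 60.1, with NfiX CD1 at its lower bound of 57.4. The log2 odds ratio was 5.23 ± 0.70 (SD, n = 6 libraries, exact sign-flip permutation p = 0.0312, the smallest possible), and Fisher's exact test passed in 6 of 6 libraries. The single NFI element TTGGCA was found at 27.0% ± 5.49 of summits and 5.55% ± 0.83 of flanks (n = 6 libraries). The same palindrome arms set 8 bases apart instead of 5 were found at 0.72% of summits and 0.297% of flanks. This control passed Fisher's exact test in 0 of 6 libraries, but its log2 odds ratio of 1.23 ± 0.40 passed across the libraries (exact sign-flip permutation p = 0.0312, n = 6). A scrambled palindrome passed in 0 of 6 libraries and was found at 0.0414% of summits and 0.069% of flanks. These windows cover only the 3.65 to 6.71% of peaks whose summits lie inside an exon.

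**Figure D4:**
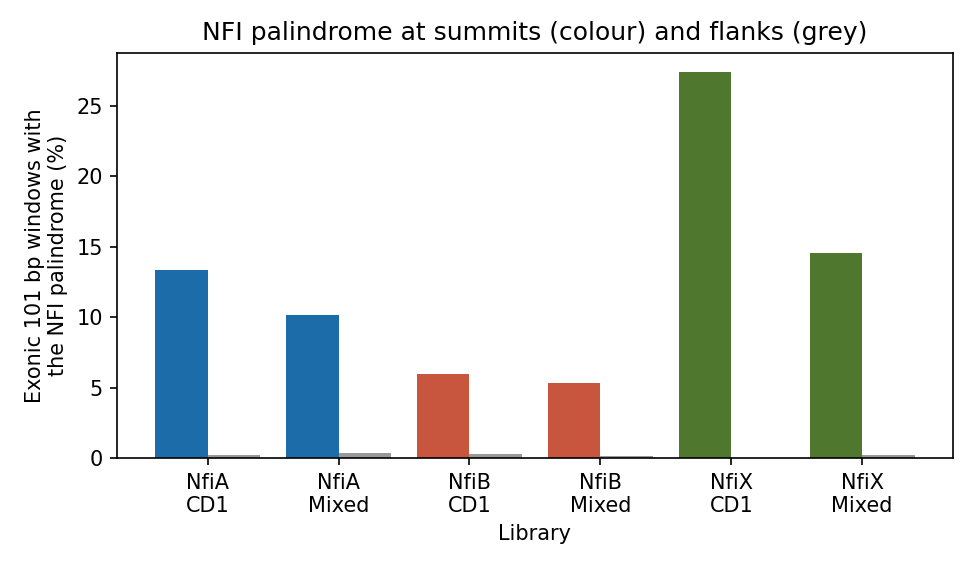
Percent of exonic windows with the NFI palindrome (vertical axis) at summits (coloured bars) and flanks (grey bars) for each library (horizontal axis). Summit shares run from 5.37% in NfiB Mixed to 27.4% in NfiX CD1, the shortest list, and flank shares stay at or below 0.365%.

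The palindrome was more frequent in regions shared by more libraries. It was present in 27.1% of common regions with an exonic window (60 of 221), 6.49% of regions in 2 to 5 libraries (112 of 1725) and 3.67% of regions in 1 library (44 of 1198). Common regions differed from regions in 1 library with an odds ratio of 9.77 (Fisher's exact test, two-sided, adjusted p = 6.56e-25). A common region must hold a peak of NfiX CD1, whose own exonic summits held the palindrome in 27.4% of cases. Peaks in common regions also had higher folds than the others. This contrast therefore cannot be told apart from list length and peak strength, and the test treats regions as independent. Flanks of common regions held the palindrome in 0 of 351 windows, so the common regions were at least 31.8-fold higher. Of the other motifs, the E-boxes CAGCTG (18.0% ± 1.45 of summits, 5.85% ± 0.89 of flanks, n = 6 libraries) and CAGATG (21.7% ± 1.55 and 7.35% ± 0.25), elements of neural bHLH factors, passed in 6 of 6 libraries. A Zic family element passed in 5 (7.46% ± 0.87 and 3.38% ± 0.44). The log2 odds ratio of this Zic element was 1.20 ± 0.09 (SD, n = 6 libraries). That was no higher than the 1.23 ± 0.40 of the control with the palindrome arms set farther apart. The Zic difference therefore cannot be told apart from the shift seen with that control. CTCF and ETS elements passed in 2 libraries each and an Sp and Klf element in 1, while a Sox element was lower at summits in 1. Gli, AP-1, CREB, RFX, Nrf1, Mef2, homeodomain, POU and TEAD elements and the E-box CACGTG passed in 0. Across the libraries, the log2 odds ratio was lower at summits in 6 of 6 for Sox (−0.32) and CACGTG (−0.29; exact sign-flip permutation p = 0.0312 for each, the smallest possible, not adjusted over the 21 motifs). Gli and CTCF elements were too rare for such a test, with 0 summit windows in 4 and 2 of the libraries. Of the 126 tests, 35 passed, 34 of them with more of the motif at summits.

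Common regions were nearest to 2502 of 21670 protein-coding genes (11.5%), with 3541 regions within 100 kb of a TSS and 2521 farther away. Genes of neuronal migration had a common region in 13 of 21 cases against 6.13 in matched random lists. Examples are Pard3, Astn2, an astrotactin of glial-guided migration (chromosome 4, 66482197 to 66483773, intergenic, folds 13.7 to 20.03), Plxna2, a semaphorin receptor, and Reln, a secreted guide of migrating neurons (chromosome 5, 22266650 to 22267510, intronic, folds 8.51 to 22.6). Axon guidance genes had one in 20 of 35 cases against 12.04, with Sema3d, Epha4 and Robo2 among the highest-ranked. Cell adhesion genes had one in 19 of 30 cases against 11.7, led by Pcdh9 (chromosome 14, 93884423 to 93884963, intronic, folds 15.3 to 29.5), Tenm4, Cadm2 and Tenm2. Genes of granule neuron differentiation had one in 12 of 23 cases against 5.91, including Stmn2, Syt1, Snap25 and Neurod1. The region of Neurod1, a transcription factor gene of differentiating granule neurons, lay in an intron of Cerkl. Members of this list without a common region included Neurod2, Gabra6, Grin2c, Cbln1, Cbln3 and Etv1. Each of these 4 lists had an adjusted p of 0.0472 in a permutation test of 10000 random lists. None of the 4 calls held with genes assigned within 10 kb (adjusted p 0.186 to 0.409, 2.77 to 3.62 times random), with genes near any peak as the background (0.26 to 0.674, 1.28 to 1.67 times) or without NfiB replicate 2 (0.0556 for each, 1.63 to 2.08 times). The ratios to random were 1.63 to 2.12 with all libraries and genes within 100 kb. Without NfiA replicate 2 neuronal migration alone was called. Axon guidance was lost without NfiA replicate 1, axon guidance and cell adhesion without NfiX replicate 1, and granule neuron differentiation and cell adhesion without NfiX replicate 2. Neuronal migration was lost with genes assigned by their bodies, granule neuron differentiation in the CD1 libraries alone, axon guidance and cell adhesion in the Mixed libraries alone, and cell adhesion at a −log10 q of 5 or more.

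**Figure D5:**
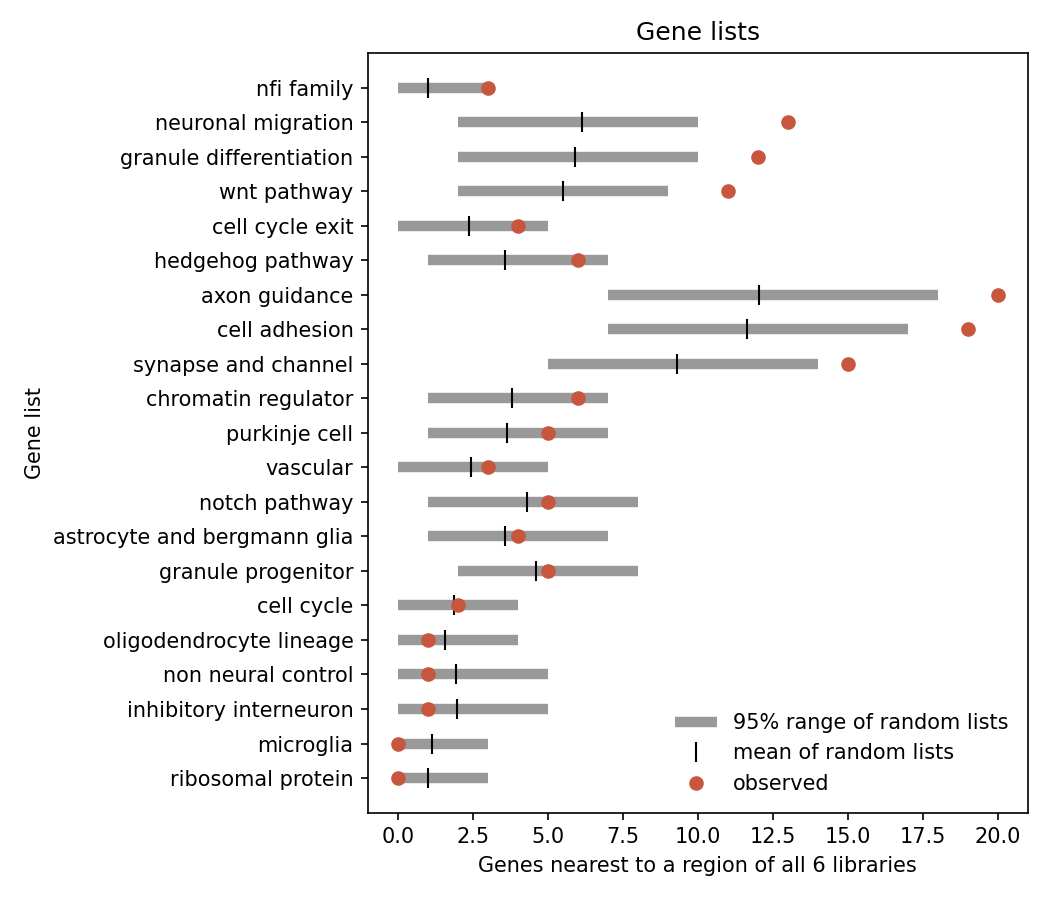
Number of genes nearest to a region common to all 6 libraries (horizontal axis) for each of the 21 gene lists (vertical axis), with observed counts as points, the mean of random lists as ticks and their 95% range as grey bars. Neuronal migration stands at 13 against 6.13 and axon guidance at 20 against 12.04.

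The other 17 lists were not called. Wnt pathway genes had a common region in 11 of 20 cases against 5.49 (permutation test, adjusted p = 0.0588; 0.0357 without NfiB replicate 1), including Apc, Wnt7a, Ctnnb1 and Wnt5a. The Wnt5a region lay in an intron of Erc2. Synapse and channel genes had a common region in 15 of 28 cases against 9.30 (permutation test, adjusted p = 0.122), led by Kcnj6 and Dlg2. Hedgehog pathway genes, which act in granule progenitor division, had one in 6 of 18 cases against 3.58 (permutation test, adjusted p = 0.571), with Cdon, Gli2 and Boc present. Ptch1, Gli1 and Smo had no common region. Ptch1 was nearest to regions with a peak in every library except NfiX CD1, Gli1 to 1 region in NfiB CD1 alone and Smo to none in any library. Markers of granule progenitors had a common region in 5 of 18 cases against 4.60 (permutation test, adjusted p = 1), with Cxcr4, Pax6, Nhlh2 and Insm1 present. The Pax6 and Insm1 regions lay in introns of Elp4 and Ralgapa2. Atoh1 had no common region but was nearest to regions with a peak in every library except NfiX CD1. Cell cycle genes had one in 2 of 26 cases against 1.85, at Cdk1 and E2f1. Cell cycle exit genes had one in 4 of 14 against 2.37, with Rbl2 ranked highest by a region in a coding exon of Chd9. Notch pathway genes had one in 5 of 23 cases against 4.29, with Hes1 first, and chromatin regulators in 6 of 20 against 3.79, with Chd7 first. Markers of other cell types were near the random level. Astrocyte and Bergmann glia genes stood at 4 of 15 against 3.56, oligodendrocyte lineage genes at 1 of 12 against 1.57, Purkinje cell genes at 5 of 13 against 3.65, inhibitory interneuron genes at 1 of 10 against 1.956 and vascular genes at 3 of 12 against 2.42. Microglial genes stood at 0 of 13 against 1.12, ribosomal protein genes at 0 of 26 against 0.991 and genes of non-neural tissues at 1 of 22 against 1.94. The astrocyte and Bergmann glia list was called when the Mixed libraries alone were used (1.87 times random, permutation test, adjusted p = 0.0196).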

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

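The test of sequencing depth below was chosen only after the result was seen. The number of peaks was higher in Mixed for NFIA and NFIX and lower for NFIB, with 1 library per factor and background, and the difference between factors was not tested. The log2 ratio of Mixed over CD1 was 1.52 for NFIX, 0.47 for NFIA and −0.13 for NFIB.

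The short NfiX CD1 list, 7497 peaks against 21443 in NfiX Mixed, was weighed against 3 explanations. The tables argue against lower depth: after the recovered NfiX Mixed fragments were thinned to the lowest local background of NfiX CD1, a ratio of 0.892, 21191 peaks still passed on average over 20 draws. NfiA CD1, with a lowest background of 0.940, below the 0.960 of NfiX Mixed, held 16993 peaks. Of the NfiX Mixed peaks missing from NfiX CD1, 80.5% (11707 of 14536) overlapped a CD1 peak of NFIA or NFIB. Sites bound in 1 background only predicted a low share. The test cannot decide this, since a NFIA or NFIB peak does not show whether NFIX bound there in CD1. The share was also near that of all NfiX Mixed peaks, 84.9% of which overlapped a NfiB CD1 peak. Weaker enrichment of the same sites in the NfiX CD1 library is a candidate explanation. Of its peaks 93.1% lay in NfiX Mixed, and recovery rose over 4 equal groups by fold from 6.83 to 15.3, 33.1 and 73.6%. Neither value is particular to this explanation. The same short list overlapped NfiB CD1 at 95.1%, and recovery rose with fold for NFIA and NFIB too. A lower NFIX occupancy in CD1 mice remains open and untested.

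Regions common to all 6 libraries could be places where chromatin is recovered without an NFI site. The palindrome speaks against that as the whole cause: the lower 95% bound of its odds ratio at exonic summits of common regions was 13.4, with the flanks at the floor of 3 counts. Whether the antibodies recognise different proteins or draw 1 common set of sites cannot be told apart, because same-factor pairs exceeded pairs of different factors by a mean Jaccard of only 0.0508 at equal list length and their ranges overlapped. Shared binding sites of the related factors are the biological alternative, and cross-reaction between antibodies was not tested.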

How the results depend on the processing

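The equal-length promoter share, the exonic motif windows and the counts of common regions without both libraries of a factor, and the pairing of backgrounds by factor, were chosen only after the results were seen. The shares of peaks recurring between backgrounds moved most with equal list lengths, to 72.1% for NFIA, 77.2% for NFIB and 67.8% for NFIX, and stayed above each of 100 random placements, a test that cannot rank them. The number of common regions, 6062, became 3350 with equal list lengths, 15890 in the Mixed libraries alone, 17283 with at least 1 library of each factor and 13136 with both NfiX libraries left out. It was 6107 to 11643 with 1 library left out, the highest without NfiX replicate 1. Regions of 1 factor alone were 24 for NFIA at a −log10 q of 5 or more. With equal lengths they were 83, 161 and 258 for NFIA, NFIB and NFIX. They were 770, 20130 and 271 in CD1 alone and 1750, 10134 and 1982 in Mixed alone, where fewer other libraries can exclude a region. The difference between same-factor pairs and pairs sharing neither factor nor background turned to −2.06 percentage points with the share of the shorter list. By the same measure it was 4.74 points with lists of equal length. Its sign thus depended on list length, and other causes were not tested. The fold difference of common peaks was 0.68 at a −log10 q of 5 or more, and 0.65 to 0.87 with 1 library left out, where 5 libraries cannot pass. The NFI palindrome log2 odds ratio was 5.09 to 5.43 with 1 library left out, for the same reason. The promoter log2 ratio was 0.61 with TSSs of all biotypes. Of the gene list calls, 0 were made with genes within 10 kb, where the 4 ratios to random were 2.77 to 3.62, and 0 with genes near any peak as background, where they were 1.28 to 1.67, and 0 to 5 lists were called with 1 library left out. Over all alternatives 283 left a call as it was or a count within a fixed ratio of its main value, a rule that uses no measured spread. Most of these were for gene lists that were not called. Of the rest, 38 fell short of the threshold, 3 came to pass it, 21 moved and 1 reversed. A value can move while its call stays: the promoter log2 ratio, not called, was 0.11 at 5 kb and 0.25 at equal list lengths. Paired by factor, Mixed minus CD1 averaged 0.62 ± 0.83 for log2 peak number, 0.33 ± 0.40 for the promoter log2 ratio and 0.23 ± 0.41 for the fold difference of common peaks (exact sign-flip permutation p = 0.5 for each, n = 3 pairs), and −0.10 ± 0.73 for the palindrome log2 odds ratio (exact permutation p = 1), where 3 pairs cannot go below 0.25. The median summit held 21 to 28 fragments, and at 0.5 of the recovered fragments a share of 0.861 to 0.888 of autosomal peaks still passed.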

Other observations

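The tests of chromosome X copy number, alone and together with gene number, were chosen only after the result was seen, as were the gene families and the ranking of genes by number of regions. Some genes gathered many common regions. Auts2, a gene linked to neurodevelopment, was nearest to 11, Prickle2, a planar cell polarity gene, to 9, Tcf20 to 8 and Chd7, a chromatin remodeller gene, to 7. Kalrn, Srgap2, Rbfox1, Runx1t1, Btbd11 and Pde4d were nearest to 6 each. Gap43, a growth cone protein gene, Dab1, which acts downstream of reelin, and Ptn were nearest to 5 each. In all, 36 genes had 5 or more. Several of these genes are nearest to long stretches of genome, 825 kb for Auts2 and 1083 kb for Rbfox1, and the counts were not tested.

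Of 18 families grouped by symbol, 3 passed the test, each with fewer genes near a common region than matched random lists. Olfactory receptor genes had one in 7 of 1134 cases against 40.9, vomeronasal receptor genes in 1 of 331 against 32.8 and zinc finger genes of the Zfp series in 21 of 397 against 40.9 (permutation test, adjusted p = 0.0012 for each, from the smallest p that 10000 random lists can give). Potassium channel genes stood at 27 of 94 against 18.3 (permutation test, adjusted p = 0.132), and the other 14 families did not pass.

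Chromosome X held fewer peaks per Mb than the autosomes in 6 of 6 libraries, at 0.207 to 0.241 of the autosomal density. Fewer genes do not account for this as the whole cause, since peaks per protein-coding gene were also lower on X, with a highest ratio of 0.367. With the recovered fragments of autosomal peaks set to 0.5 of their number, a share of 0.861 to 0.888 still passed, and X density was at most 0.338 of what that would leave on the sparsest autosome. With the lower gene density added, it was at most 0.415. Mappability and repeat content of X and the sex of the animals were not tested, and each may contribute.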
